A study of Homo sapiens with 10 samples.

How the data were processed

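RNA was sequenced from CD14+ monocytes of 5 donors, 3 with a myeloproliferative neoplasm (MPN) and 2 healthy, each treated with α-ketoglutarate (α-KG) or with its solvent dimethyl sulfoxide (DMSO), giving 10 libraries. Per the labels' protocols, total RNA was isolated with a column kit and a DNase step and sequenced on an Illumina instrument. The dose and length of treatment, the library kit, the selection of RNA, the strand of the reads and the gene annotation are not given in the sources used here. Per the submitters' processing notes, reads were handled with bcl2fastq and DRAGEN on the genome build GRCh38, without stated versions. The deposited table holds expected counts per gene from the authors, not scaled to depth, for 59653 gene names. Between 9.22% and 11.5% of the values in a library were not whole numbers at a tolerance of 0.001, so all values were rounded to whole numbers before every test.

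Totals ran from 13860422 to 24189557 counts per library, and counts are given as CPM, counts scaled to a common library total. Gene names were matched to GENCODE v29, which held 55022 (92.2%) of them and gave the coordinates and gene types. Of 837 members of the gene lists, 2 were matched by an older name and 0 were missing from the table. Y-linked genes, XIST and TSIX, 507 in all, were left out of every test. All columns of the table were used.

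An α-KG and a DMSO library were taken as a pair where their titles shared a donor code, and each donor served as a replicate block. As a check, the deviation of each library from its group's mean was correlated across genes with those of the other treatment's libraries, and for the 3 MPN donors the best match was the library of the same donor. For the 2 healthy donors these deviations mirror each other, so their match (r = 0.237) is a single outcome. Libraries of the same group correlated across genes at r of 0.914 to 0.951 in log2 CPM.

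Differences were tested in R 4.3.3 with edgeR 4.0.16, using trimmed mean of M-values (TMM) scaling, the default low-count filter (a minimum count of 10 and a minimum total of 15) and the quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg (BH) with a threshold of 0.05. Values called SE are standard errors of the log2 fold change, derived from the F statistic. An SE given with a list's median is taken over its members, so it treats genes as independent and does not measure the spread between donors. A model of donor plus treatment within each donor group, over all 10 libraries, gave the effect of α-KG in MPN (3 pairs), in healthy donors (2 pairs) and the difference of these effects. A model of donor plus treatment gave the effect over all 5 pairs. MPN and healthy monocytes were compared within the 5 DMSO libraries and, separately, within the 5 α-KG libraries. The treatment models tested 18433 genes, the DMSO comparison 16794 and the α-KG comparison 16463.

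Before the data were examined, 37 gene lists were written from textbook knowledge. They covered signalling (NF-kB targets, inflammatory cytokines and chemokines, interferon-stimulated genes, JAK-STAT targets, immediate early genes, p53 targets), stress (ATF4 amino-acid response, NRF2 antioxidant targets, heat shock, unfolded protein response, hypoxia targets, metallothioneins) and metabolism (sterol synthesis, LXR targets, glycolysis, TCA cycle and α-KG enzymes, nuclear and mitochondrial genes of oxidative phosphorylation, 2-oxoglutarate-dependent dioxygenases). They also covered ribosomal proteins, proliferation, MHC class II presentation, coagulation, alternative activation, complement, lysosome and autophagy. Cell type lists held markers of classical and non-classical monocytes, maturing macrophages, dendritic, T, NK and B cells, neutrophils, platelets, erythroid cells and haematopoietic progenitors. Each list was tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01), adjusted by BH over the 37 lists, beside camera with an estimated correlation and fry. Counts of members past the threshold are given over all genes and adjusted over the list alone.

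Also fixed before the data were examined was which genes are named. Eligible genes had a gene symbol of a known kind (no clone, antisense, small RNA or pseudogene names) and a mean log2 CPM of at least 1. Genes that can show a person's sex or genotype were excluded. The 12 rising and 12 falling genes of largest fold change, past the threshold and moving the same way in every pair, were taken for the effect of α-KG in MPN and over all donors, and 5 of each for the other comparisons. Where no gene passed, the 5 higher and 5 lower genes of smallest p were taken. Up to 4 members of smallest p per list and genes of interest, of which TNF, IL1B, IL6, CXCL8, CCL2, IL10, OSM, SOCS3, ASNS and HMOX1 are used here, were added. A gene that the rule chose but that is not used here is not named. H1-1, DNAJB1 and EGR1 in the plot of donor pairs are among the genes so named, and were picked for it after their values were seen.

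For a group with 0 counts of a gene, a floor of 3 counts over the group gave a bound on the fold between group means. It covers counting error only, not the spread between donors. The whole procedure was tested on simulated data with the same libraries' means and spread, in which 200 genes were changed, 67 of them 1.5-fold, 67 2-fold and 66 4-fold. Of the genes changed 4-fold it recovered 92.4% for α-KG in MPN, 80.3% in healthy donors, 65.2% for the difference of effects, 98.5% over all donors, 57.6% for disease in DMSO and 34.8% for disease in α-KG. Of those changed 2-fold the shares were 55.2%, 37.3%, 17.9%, 73.1%, 2.99% and 2.99%. False calls in the same order were 11 of 122 calls, 5 of 87, 12 of 68, 12 of 146, 7 of 48 and 1 of 26.

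Alternatives were run singly, although DESeq2 and limma-voom replace several steps together and fits on other sets of libraries redo the low-count filter. They were DESeq2's scaling (RLE), library totals alone, no low-count filter, a stricter filter of 1 CPM, the Wald test of DESeq2 1.42.0, limma-voom, no replicate block, each donor group's own libraries, all 10 libraries for the disease comparisons, and each donor left out in turn. Leaving out rRNA-like and mitochondrial genes, and leaving out each donor from the correlation of effects, were chosen after seeing the data. RNA composition was compared between treatments with an exact sign-flip test over the 5 pairs, 2-sided, whose smallest possible p is 0.0625.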

Results

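Gene expression was measured by RNA sequencing in CD14+ monocytes, the blood cells that mature into macrophages, from donors with an MPN (a group of clonal blood cancers that overproduce mature blood cells) and from healthy donors. Each donor gave a library of cells treated with α-KG, an intermediate of the TCA cycle and co-substrate of many dioxygenases, and a library of cells in DMSO. There were 3 MPN and 2 healthy donors, hence 10 libraries. Totals per library ran from 13860422 to 17338631 counts for MPN with α-KG (n = 3) and from 14153107 to 19001465 for MPN in DMSO (n = 3), and were 15714660 and 17891532 for healthy with α-KG (n = 2) and 17444983 and 24189557 for healthy in DMSO (n = 2).

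The make-up of the RNA was compared between treatments, as was the total. Total counts with α-KG were lower in 5 of 5 donors, by a mean change of -2501295 ± 2322589 counts (SD, n = 5 pairs, exact sign-flip test, p = 0.0625). Counts of rRNA-like genes, annotated in ribosomal DNA clones of chromosome 21, took 3.18 ± 2.65 percentage points more of a library with α-KG than in DMSO (SD, n = 5 pairs), higher in 5 of 5 donors (exact sign-flip test, p = 0.0625, the smallest it can give). Mitochondrial rRNA took 1.58 ± 1.29 points more, higher in 4 of 5 donors (exact sign-flip test, p = 0.125), and mitochondrial mRNA and tRNA 1.51 ± 1.28 points more, higher in 5 of 5 (p = 0.0625, exact test), though in healthy replicate 2 it was 7.46% with both treatments. Protein-coding genes took less in 5 of 5 donors, by a mean change of -5.46 ± 3.64 points (exact sign-flip test, p = 0.0625).

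The effect of α-KG on monocytes of patients bears on the series' theme of metabolism and inflammation in MPN. With α-KG, interferon-stimulated genes fell steeply. IFIT1, an antiviral protein that binds foreign RNA (chromosome 10, 89392546 to 89406486, plus strand, GRCh38), fell 23.1-fold, from 26.7 ± 18 CPM (SD, n = 3) in DMSO to 1.17 ± 0.865 CPM (SD, n = 3) (log2 fold change -4.53 (SE 0.24), edgeR, BH adjusted p = 1.44e-08). CXCL10, an interferon-induced chemokine that attracts T cells (chromosome 4, 76021117 to 76023497, minus strand), fell 12-fold, from 22.3 ± 14.4 CPM (SD, n = 3) to 1.76 ± 1.34 CPM (SD, n = 3). In the other direction RPL3L, a ribosomal protein known from muscle (chromosome 16, 1943974 to 1957606, minus strand), rose 13.9-fold, from 0.57 ± 0.135 CPM (SD, n = 3) to 7.87 ± 1.3 CPM (SD, n = 3), and the linker histone gene H1-1 rose 6.32-fold, from 2.45 ± 1.18 CPM (SD, n = 3) to 16.2 ± 8.55 CPM (SD, n = 3).

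Of 18433 genes, 538 were higher and 696 lower with α-KG in MPN monocytes (edgeR, BH threshold of 0.05). Protein-coding genes made up 327 of the higher and 653 of the lower, and 355 and 294 changed at least 2-fold. With library totals in place of TMM, which moved the median of all genes to -0.16, the split was 390 higher and 1101 lower. Without the replicate block 84 genes passed, without MPN replicate 1 there were 798, and without MPN replicate 2 there were 688.

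Of the 12 rising genes named by the rule, 6 were histone genes. These were H3C15 (3.45 (SE 0.28)), H1-6 (3.17 (SE 0.61)), H3C11 (3.08 (SE 0.46)), H4C15 (3.05 (SE 0.27)), H3C7 (2.72 (SE 0.48)) and H1-1 (2.66 (SE 0.32)), given as log2 fold change. The remaining risers used here were RPL3L (3.80 (SE 0.46)), STOML1 (3.08 (SE 0.39)), MYEOV (2.84 (SE 0.27)), the long non-coding RNA UCA1 (2.71 (SE 0.42)) and AMT of the glycine cleavage system (2.69 (SE 0.27)). The falling genes held the interferon-induced IFIT1, IFIT3 (-4.03 (SE 0.23)), OAS3 (-3.15 (SE 0.34)), CMPK2 (-2.91 (SE 0.30)), USP18 (-2.85 (SE 0.55)) and SAMD9L (-2.79 (SE 0.22)), the chemokines CXCL10 (-3.58 (SE 0.28)) and CCL8 (-2.66 (SE 0.45)), and the tryptophan-degrading enzyme IDO1 (-3.48 (SE 0.36)). ADAMDEC1 (-2.91 (SE 0.28)), the receptor antagonist IL36RN (-2.86 (SE 0.64)) and the signalling ligand WNT5A (-2.66 (SE 0.35)) completed them. BH adjusted p for the 24 genes of the rule ran from 1.44e-08 for IFIT1 to 0.0103 for IL36RN, and 22 passed with each donor left out in turn. IL36RN did not pass without MPN replicate 1 (adjusted p = 0.148) nor USP18 without MPN replicate 2 (adjusted p = 0.0663).

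H3C15 and H4C15 have near-identical copies, H3C14 and H4C14, and RPL3L resembles the abundant RPL3 (log2 fold change 0.16 (SE 0.14), not passing), so a read can be assigned to either gene of such a pair. IFIT1 and IFIT3 lie opposite LIPA, which had a log2 fold change of -0.92 (SE 0.26) (adjusted p = 0.0435, and 0.275, 0.0552 and 0.138 without MPN replicate 1, 2 and 3), and the strand of the reads is not given. IFIT2 also lies opposite LIPA, CXCL10 opposite ART3 and CMPK2 opposite RSAD2.

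All 36 interferon-stimulated genes had negative log2 fold changes in MPN, with a median of -1.63. By the test of each gene 28 fell and 8 did not pass, and 34 were lower when adjusted over the list alone. The camera adjusted p was 9.49e-67, with adjusted p = 0.274 with an estimated correlation. Heat shock genes, the chaperones of misfolded protein, went up, 11 of 15 (13 when adjusted over the list alone, median 0.88, camera adjusted p = 3.32e-20, adjusted p = 0.27 with an estimated correlation). Among them were DNAJB1 (1.62 (SE 0.14)), CRYAB (2.05 (SE 0.23)) and HSP90AA1 (1.12 (SE 0.15)). Of 22 immediate early genes, the first transcription factors switched on by stimuli, 12 rose and 0 fell (17 higher and 1 lower when adjusted over the list alone, median 0.60), with camera adjusted p = 5.52e-15 and adjusted p = 0.141 with an estimated correlation. EGR1 (1.88 (SE 0.26)), NR4A2 (1.38 (SE 0.16)) and FOSB (1.23 (SE 0.16)) were among these. With donors left out, heat shock genes that rose numbered 7 without MPN replicate 3, and immediate early genes that rose 7 without MPN replicate 3.

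NRF2 antioxidant targets fell together, 12 of 19 (15 when adjusted over the list alone, median -0.66, camera adjusted p = 3.28e-12, adjusted p = 0.292 with an estimated correlation). NQO1, a quinone reductase (-1.17 (SE 0.17)), GCLC of glutathione synthesis (-0.88 (SE 0.14)), glutathione reductase GSR (2.01-fold) and haem oxygenase HMOX1 (-0.81 (SE 0.14)) fell. The count of falling NRF2 targets was 7 without MPN replicate 1 and 6 without MPN replicate 2. Mitochondrially encoded subunits of oxidative phosphorylation were up, 7 of 13 (9 when adjusted over the list alone, median 0.53, camera adjusted p = 1.01e-07, adjusted p = 0.418 with an estimated correlation), beside the larger share of mitochondrial RNA in the α-KG libraries. MT-ND5 rose by 0.76 (SE 0.14) and MT-ND4L by 0.71 (SE 0.14), and neither passed without MPN replicate 2 (adjusted p = 0.0542 and 0.0719). The number of these subunits higher was 0 without MPN replicate 2, 3 without MPN replicate 3 or healthy replicate 1 and 2 without healthy replicate 2. Among the 77 nuclear-encoded subunits 1 fell, SDHC (-0.73 (SE 0.18)), which did not pass without MPN replicate 1 (adjusted p = 0.196) or 3 (0.0698). No other member passed, 0 when adjusted over the list alone, with camera adjusted p = 0.549. With donors left out, the nuclear-encoded subunits higher numbered 3 without MPN replicate 3, and those lower 0 without MPN replicate 1 and 2 without MPN replicate 2.

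TCA cycle and α-KG enzymes included 5 that fell and 36 that did not pass (6 lower when adjusted over the list alone, median -0.31, camera adjusted p = 0.00251, adjusted p = 0.342 with an estimated correlation). DLD, the shared subunit of the pyruvate and α-KG dehydrogenases, fell by 1.01 on the log2 scale (SE 0.18, adjusted p = 0.00172). The number of these enzymes lower was 1 without MPN replicate 1, 3 without MPN replicate 2 and 2 without MPN replicate 3. Glycolysis genes had 4 that fell of 22 (6 when adjusted over the list alone, median -0.24, camera adjusted p = 0.0121, adjusted p = 0.387 with an estimated correlation). Enolase ENO1 (-0.69 (SE 0.15)) fell, and did not pass without MPN replicate 1 (adjusted p = 0.0639). The count of glycolysis genes that fell was 0 without MPN replicate 1 and 1 without MPN replicate 3 or either healthy donor.

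NF-kB targets moved both ways, with 3 higher, 8 lower and 14 not passing (4 higher and 12 lower when adjusted over the list alone, median -0.38, camera adjusted p = 0.00251, adjusted p = 0.614 with an estimated correlation). The adhesion molecule ICAM1 (-1.33 (SE 0.16)) and the feedback inhibitor TNIP1 (-1.23 (SE 0.15)) fell, whereas the prostaglandin synthase PTGS2 rose (1.37 (SE 0.18)). Inflammatory cytokines and chemokines had 4 higher, 5 lower and 18 not passing (7 higher and 5 lower when adjusted over the list alone, median -0.10, camera adjusted p = 0.413). CXCL10, CCL8 and CCL4 (-2.29 (SE 0.28)) fell. TNF (0.15 (SE 0.26)), IL1B (-0.25 (SE 0.26)), IL6 (-0.58 (SE 0.87)), CXCL8 (0.48 (SE 0.17)), CCL2 (-0.10 (SE 0.20)), IL10 (0.70 (SE 0.25)) and OSM (0.28 (SE 0.19)) did not pass. Nor did SOCS3 (0.25 (SE 0.25)) or ASNS (-0.72 (SE 0.28)). Lower NF-kB targets numbered 3 without MPN replicate 1 or 2, and higher cytokines 2 without MPN replicate 3. The NF-kB median without MPN replicate 1 was -0.22, and that of cytokines changed sign, to 0.22, as it did without MPN replicate 3 (0.07), while without MPN replicate 2 it was -0.20.

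Another 4 lists passed with camera in the downward direction and 2 in the upward one. Among p53 targets 4 of 18 fell (4 when adjusted over the list alone, camera adjusted p = 0.00201, adjusted p = 0.287 with an estimated correlation), with the DNA repair gene DDB2 (-1.45 (SE 0.18)) and the apoptosis gene BAX (-0.91 (SE 0.16)). Complement genes had 2 that fell of 15, the receptor C3AR1 (-1.43 (SE 0.19)) and C3 (-0.98 (SE 0.16)), and 4 when adjusted over the list alone (camera adjusted p = 0.0048, adjusted p = 0.292 with an estimated correlation). Coagulation genes had 2 that fell of 17, the ATP receptor P2RX7 (-1.14 (SE 0.18)) and the protein C receptor PROCR (-1.76 (SE 0.29)), with 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.0112, adjusted p = 0.38 with an estimated correlation). Macrophage maturation markers had 1 higher, 6 lower and 9 not passing (2 higher and 6 lower when adjusted over the list alone, median -0.56, camera adjusted p = 0.00171, adjusted p = 0.292 with an estimated correlation), with SPP1 (-1.89 (SE 0.29)) and CD9 (-1.62 (SE 0.17)) falling. Platelet and megakaryocyte markers had 0 of 19 past the threshold and 0 when adjusted over the list alone, with positive log2 fold changes for 18 (median 0.57, camera adjusted p = 0.0025, adjusted p = 0.387 with an estimated correlation). Ribosomal protein genes also had 0 of 78 past the threshold, 0 over the list alone and a median of 0.11 (camera adjusted p = 0.00526, adjusted p = 0.777 with an estimated correlation), which turned to -0.03 with library totals. With donors left out, the p53 targets that fell numbered 2 without any 1 of the 5 donors. Maturation markers that were lower numbered 3 without MPN replicate 3, and higher ones 0 without MPN replicate 1 or 2 and 2 without MPN replicate 3. Of coagulation genes 1 was higher without MPN replicate 1. The platelet median was 0.25 without MPN replicate 2, and the ribosomal one 0.25 without MPN replicate 1 and 0.04 without MPN replicate 2.

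The other 23 lists did not pass with camera in MPN. LXR targets had 0 higher, 3 lower and 8 not passing (camera adjusted p = 0.0834), with the cholesterol exporter ABCA1 falling (-1.04 (SE 0.16)). Hypoxia targets had 0 higher, 4 lower and 21 not passing (camera adjusted p = 0.132), among them AK4 (-1.74 (SE 0.22)). ATF4 targets had 4 higher, 3 lower and 22 not passing (camera adjusted p = 0.806), DDIT4 rising (0.95 (SE 0.19)) and the serine enzyme SHMT2 falling (-0.73 (SE 0.17)). DDIT4 did not pass without MPN replicate 1 (adjusted p = 0.0507) or 2 (0.0631), nor SHMT2 without MPN replicate 1 (0.112) or 3 (0.0636). The unfolded protein response had 2 higher, 0 lower and 17 not passing (camera adjusted p = 0.132), with HERPUD1, which helps clear misfolded protein, rising (1.81 (SE 0.17)). Lysosome and autophagy genes had 1 higher, 5 lower and 23 not passing (camera adjusted p = 0.132), the protease CTSL (-0.82 (SE 0.14)) falling. Alternative activation genes had 2 higher, 2 lower and 14 not passing (camera adjusted p = 0.549), the scavenger receptor MSR1 rising (0.91 (SE 0.22)) and the transglutaminase TGM2 falling (-1.64 (SE 0.40)). MSR1 did not pass without MPN replicate 1 (adjusted p = 0.148) or 2 (0.11), nor TGM2 without MPN replicate 2 (0.0524) or 3 (0.142). Counts of these 6 lists also hung on single donors. LXR targets that fell numbered 1 without MPN replicate 2 or 3, and hypoxia targets 2 without MPN replicate 1 or 3 or either healthy donor. ATF4 targets had a higher count of 2 without MPN replicate 1 and 0 without MPN replicate 2, and a lower count of 1 without MPN replicate 1. The unfolded protein response had a higher count of 1 without MPN replicate 2 or 3. Lysosome genes had a lower count of 3 without MPN replicate 1 or 3, and a higher count of 2 without MPN replicate 2. Alternative activation genes had a higher count of 0 without MPN replicate 1 or 2, and a lower count of 1 without MPN replicate 1 and 0 without MPN replicate 2 or 3.

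Smaller numbers moved in the remaining lists. JAK-STAT targets had 0 higher, 1 lower and 17 not passing (camera adjusted p = 0.806), the member that fell being MYC (-1.17 (SE 0.32)), which did not pass without MPN replicate 2 (adjusted p = 0.204) or 3 (0.161). Sterol synthesis had 0 higher, 1 lower and 24 not passing (camera adjusted p = 0.806), with EBP lower (-0.60 (SE 0.17), and adjusted p from 0.0504 to 0.368 with any 1 of the 5 donors left out). Proliferation genes had 1 higher, 0 lower and 21 not passing (camera adjusted p = 0.443), RRM2 rising (2.37 (SE 0.62)), though not without MPN replicate 1 (adjusted p = 0.305) or 3 (0.0799). None of 46 dioxygenases (camera adjusted p = 0.806), 12 MHC class II genes (camera adjusted p = 0.455) or 3 metallothioneins (camera adjusted p = 0.443) passed. Classical monocyte markers had 1 higher, 2 lower and 10 not passing (camera adjusted p = 0.184), with CD14 (-0.60 (SE 0.16)) and CD36 (-0.88 (SE 0.20)) falling and MNDA rising (0.77 (SE 0.21)). Without MPN replicate 1 none of CD14, CD36 and MNDA passed (adjusted p = 0.188, 0.0983 and 0.185), without MPN replicate 2 MNDA did not (0.257), and without MPN replicate 3 CD14 and CD36 did not (0.0684 and 0.156), nor CD14 without either healthy donor (0.0571 and 0.0711). Non-classical markers had 2 higher, 2 lower and 7 not passing (camera adjusted p = 0.443), LILRB1 (-1.25 (SE 0.17)) and RHOC (-0.80 (SE 0.14)) falling. The higher count of non-classical markers was 0 without MPN replicate 1 and 1 without MPN replicate 2 or 3. Markers of other cells gave 1 of 13 lower for dendritic cells, XCR1 (-3.17 (SE 0.66)), 1 of 15 lower for T cells, CD3G (-0.87 (SE 0.23)), and 1 of 7 higher for progenitors, SOX4 (1.60 (SE 0.20)). XCR1 did not pass without MPN replicate 1 (adjusted p = 0.055) or 2 (0.08), nor CD3G without MPN replicate 1 (0.252), 2 (0.0577) or 3 (0.118). No NK (of 15), B cell (of 11), neutrophil (of 10) or erythroid (of 5) marker passed, and camera adjusted p for these 7 cell type lists outside the monocyte lineage ran from 0.184 to 0.948.

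**Figure D1:**
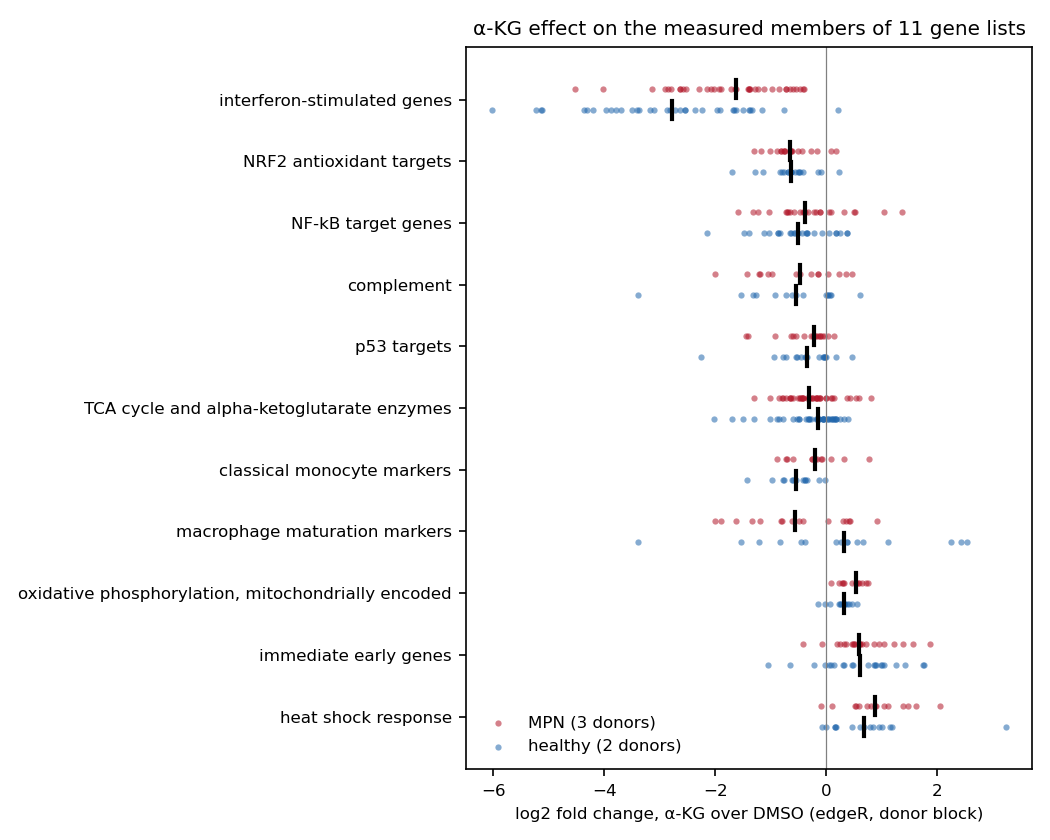
Log2 fold change of α-KG over DMSO for each measured member of 11 gene lists, MPN above in red (3 donors) and healthy below in blue (2 donors), with the median of each list as a black bar. The interferon-stimulated genes lie furthest to the left, with medians of -1.63 in MPN and -2.77 in healthy monocytes, and the heat shock genes furthest to the right, with medians of 0.88 and 0.68.

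In healthy monocytes the same comparison gives the background against which the patients' response can be set. Interferon-stimulated genes fell here too: IFIT3 fell 37.3-fold, from 695 ± 315 CPM (SD, n = 2) in DMSO to 17.8 ± 4.14 CPM (SD, n = 2) with α-KG (log2 fold change -5.22 (SE 0.29), edgeR, BH adjusted p = 1.71e-08). CCL8, a monocyte-attracting chemokine, fell 60.2-fold and USP18, which removes the interferon-induced modifier ISG15, fell 65-fold. The organic anion transporter SLCO2B1 rose 25.9-fold, from 0.474 ± 0.359 CPM (SD, n = 2) to 12 ± 5.34 CPM (SD, n = 2), and the small chaperone CRYAB rose 9.47-fold. H4C6 (4.56 (SE 0.67)) and H3C15 (3.33 (SE 0.33)) were other risers that the rule chose. The read-through transcript ZNF625-ZNF20 had 0 counts with α-KG and was at least 29.6-fold lower than in DMSO (16.7-fold without healthy replicate 1). It overlaps ZNF625 and ZNF20 on the same strand, so a read can be assigned to either of these instead, which the floor does not cover. The long non-coding RNA PRAL, opposite XAF1, fell by 5.36 on the log2 scale.

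In all, 372 genes were higher and 437 lower of 18433 (edgeR, BH threshold of 0.05). Without the replicate block 3 passed, and with the healthy libraries alone 1384. Without healthy replicate 1 the count was 170, and PRAL no longer passed (adjusted p = 0.0554). Without healthy replicate 2 it was 438.

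Of the 36 interferon-stimulated genes 33 fell in healthy monocytes (34 when adjusted over the list alone), with a median of -2.77, camera adjusted p = 2.05e-129 and adjusted p = 0.14 with an estimated correlation. NRF2 targets had 7 that fell of 19 (15 over the list alone, median -0.64, camera adjusted p = 4.72e-09, adjusted p = 0.313 with an estimated correlation). Heat shock genes had 6 that rose of 15 (median 0.68, camera adjusted p = 4.54e-11, adjusted p = 0.296 with an estimated correlation). Immediate early genes had 8 higher, 2 lower and 12 not passing (median 0.62, camera adjusted p = 7.21e-09, adjusted p = 0.14 with an estimated correlation), with FOSB (1.42 (SE 0.20)) and KLF2 (1.74 (SE 0.30)) rising. FOSB and KLF2 did not pass without healthy replicate 1 (adjusted p = 0.0973 and 0.151). Leaving out a healthy donor lowered these counts. NRF2 targets that fell numbered 0 without healthy replicate 1 and 1 without healthy replicate 2, heat shock genes that rose 1 without healthy replicate 1 and 3 without healthy replicate 2, and immediate early genes that rose 0 without healthy replicate 1 and 5 without healthy replicate 2. The lower count of immediate early genes was 1 without MPN replicate 2 or 3 and 0 without either healthy donor.

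NF-kB targets had 0 higher, 7 lower and 18 not passing (median -0.50, camera adjusted p = 3.31e-07, adjusted p = 0.492 with an estimated correlation). Cytokines and chemokines had 4 higher, 5 lower and 18 not passing (median -0.62, camera adjusted p = 0.00112, adjusted p = 0.296 with an estimated correlation). CXCL10 (-4.63 (SE 0.32)) and CCL2, the main monocyte chemoattractant (-1.69 (SE 0.24)), fell, and IL10, an anti-inflammatory cytokine, rose (1.12 (SE 0.30)). CCL2 did not pass without healthy replicate 1 (adjusted p = 0.0645), nor IL10 without healthy replicate 1 (0.706) or 2 (0.0609). Classical monocyte markers had 0 higher, 5 lower and 8 not passing (median -0.55, camera adjusted p = 5.93e-06, adjusted p = 0.296 with an estimated correlation). Non-classical markers had 0 higher, 3 lower and 8 not passing (camera adjusted p = 0.000529, adjusted p = 0.296 with an estimated correlation). The other 3 lists that passed with camera were mitochondrially encoded subunits with 0 of 13 past the threshold (median 0.31, 0.0104, and adjusted p = 0.719 with an estimated correlation), complement with 3 that fell (0.0116, and adjusted p = 0.296 with an estimated correlation) and p53 targets with 1 that fell (0.03, and adjusted p = 0.306 with an estimated correlation). Here too the counts hung on the 2 healthy donors. Lower NF-kB targets numbered 2 without healthy replicate 1 and 4 without healthy replicate 2, higher cytokines 0 without healthy replicate 1 and 2 without healthy replicate 2, and lower classical markers 1 without either healthy donor. Non-classical markers that fell numbered 1 without healthy replicate 1, complement genes 0 without healthy replicate 1 and 1 without healthy replicate 2, and p53 targets 0 without either healthy donor. Without healthy replicate 2 the median was -0.33 for NF-kB targets and -0.22 for cytokines, and without healthy replicate 1 it was 0.16 for mitochondrially encoded subunits.

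Over all 5 donors, the comparison asks which responses to α-KG were shared. IFIT1 fell 28.7-fold (log2 fold change -4.84 (SE 0.19), n = 5 pairs, edgeR, BH adjusted p = 8.78e-10), and so did IFIT3 (-4.53 (SE 0.25)), CXCL10 (-4.11 (SE 0.25)), USP18 (-4.06 (SE 0.60)), CCL8 (-4.05 (SE 0.54)), IDO1 (-3.58 (SE 0.28)) and OAS3 (-3.50 (SE 0.28)). MX1, which blocks influenza virus (-3.33 (SE 0.33)), OAS2 (-3.33 (SE 0.38)), IFIT2 (-3.31 (SE 0.48)), SAMD9L (-3.14 (SE 0.21)) and CMPK2 (-3.03 (SE 0.22)) completed the 12 falling genes named by the rule. RPL3L (3.55 (SE 0.35)), SLCO2B1 (3.06 (SE 0.45)), MYEOV (2.92 (SE 0.21)), STOML1 (2.76 (SE 0.30)), the growth factor receptor ERBB3 (2.64 (SE 0.25)) and UCA1 (2.61 (SE 0.32)) rose. With them rose the histone genes H3C15 (3.40 (SE 0.20)), H4C6 (3.20 (SE 0.47)), H3C7 (2.75 (SE 0.36)), H1-6 (2.72 (SE 0.45)) and H3C14 (2.67 (SE 0.24)), of which H3C14 and H3C15 are copies of each other. The rule takes only genes that move the same way in every pair, so that trait of the 24 is no result. All 24 passed with each donor left out in turn, but they were chosen as the largest changes in these same donors.

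In total 880 genes were higher and 1097 lower of 18433 (edgeR, BH threshold of 0.05), against 657 and 1524 with library totals, which moved the median of all genes to -0.12. Without the replicate block 318 passed, and without healthy replicate 1 there were 1272.

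Interferon-stimulated genes had 34 that fell of 36 over all donors (35 over the list alone, median -1.95, camera adjusted p = 5.84e-80, adjusted p = 0.137 with an estimated correlation). Immediate early genes had 12 higher, 1 lower and 9 not passing (15 higher and 1 lower when adjusted over the list alone, median 0.52, camera adjusted p = 2.87e-15), and theirs was the only list still past the threshold with an estimated correlation (adjusted p = 0.0455). Heat shock genes had 12 that rose of 15 (median 0.79, camera adjusted p = 3.89e-17, adjusted p = 0.127 with an estimated correlation), and NRF2 targets 14 that fell of 19 (median -0.66, camera adjusted p = 1.01e-13, adjusted p = 0.175 with an estimated correlation). HMOX1 fell by 0.74 on the log2 scale (SE 0.10) and IL10 rose by 0.87 (SE 0.19). ASNS, which makes asparagine, fell by 0.72 on the log2 scale (adjusted p = 0.0404), but did not pass without healthy replicate 1 (adjusted p = 0.215) or any MPN replicate (0.145, 0.108 and 0.0523).

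Other lists past the threshold over all donors pointed down. NF-kB targets had 3 higher, 11 lower and 11 not passing (camera adjusted p = 5e-06, adjusted p = 0.533 with an estimated correlation), TCA cycle enzymes 6 that fell (camera adjusted p = 0.0036, adjusted p = 0.219 with an estimated correlation) and glycolysis 1 higher, 6 lower and 15 not passing (camera adjusted p = 0.0355, adjusted p = 0.533 with an estimated correlation). P53 targets had 5 that fell (camera adjusted p = 0.00189, adjusted p = 0.163 with an estimated correlation), complement 4 (camera adjusted p = 0.00302, adjusted p = 0.163 with an estimated correlation) and coagulation 5 (camera adjusted p = 0.0355, adjusted p = 0.37 with an estimated correlation). Classical monocyte markers had 5 that fell (camera adjusted p = 0.0036, adjusted p = 0.533 with an estimated correlation) and non-classical markers 2 higher, 3 lower and 6 not passing (camera adjusted p = 0.0355, adjusted p = 0.556 with an estimated correlation). Upward calls went to mitochondrially encoded subunits, with 8 that rose (camera adjusted p = 2.44e-06, adjusted p = 0.533 with an estimated correlation), and platelet markers, with PPBP (0.70 (SE 0.17)) and CAVIN2 (0.91 (SE 0.27)) rising (camera adjusted p = 0.0036, adjusted p = 0.512 with an estimated correlation). PPBP did not pass without healthy replicate 1 (adjusted p = 0.0706) or MPN replicate 2 (0.0878), nor CAVIN2 without healthy replicate 1 (0.0977) or 2 (0.0761) or MPN replicate 1 (0.0623) or 2 (0.163). Ribosomal protein genes had 0 past the threshold (camera adjusted p = 0.0187, adjusted p = 0.839 with an estimated correlation), with a median of 0.09 that turned to -0.01 with library totals. With donors left out, TCA cycle enzymes that fell numbered 2 without MPN replicate 1 or healthy replicate 1. Glycolysis genes that were lower numbered 3 without healthy replicate 1, and higher ones 2 without MPN replicate 1 and 0 without MPN replicate 2 or either healthy donor. Higher NF-kB targets numbered 5 without MPN replicate 1, lower classical markers 3 without either healthy donor, and higher non-classical ones 1 without MPN replicate 1 or 2. Mitochondrially encoded subunits that rose numbered 3 without MPN replicate 2 and 4 without healthy replicate 1. The ribosomal median was 0.16 without MPN replicate 1 and 0.06 without MPN replicate 2.

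**Figure D2:**
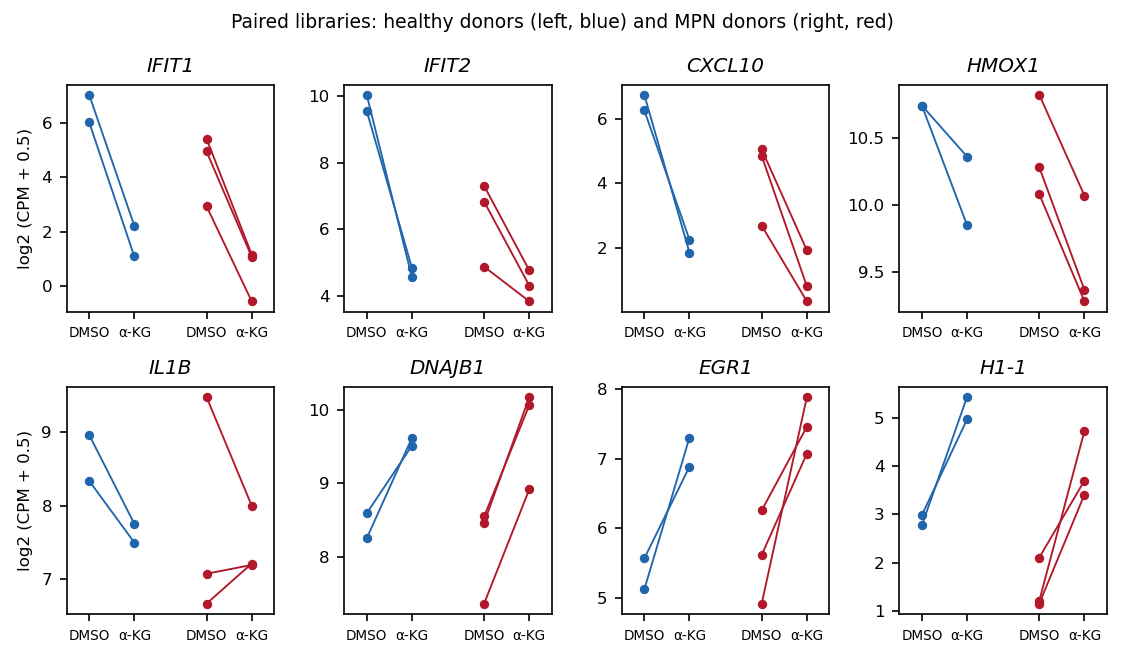
Level of 8 genes in each library, as log2 of CPM plus 0.5, in healthy (left, blue, 2 donors) and MPN monocytes (right, red, 3 donors), with lines joining the DMSO and α-KG libraries of a donor. IFIT1, IFIT2, CXCL10 and HMOX1 go down and DNAJB1, EGR1 and H1-1 go up in all 5 donors, while IL1B goes both ways.

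Whether MPN and healthy monocytes responded differently was tested by the difference of the effects, MPN minus healthy. IFIT2, an antiviral protein of the IFIT family (chromosome 10, 89283694 to 89309276, plus strand), fell less in MPN. It went from 906 ± 214 CPM (SD, n = 2) to 25.6 ± 3.63 CPM (SD, n = 2) in healthy cells and from 100 ± 65.5 CPM (SD, n = 3) to 19.8 ± 6.47 CPM (SD, n = 3) in MPN cells (log2 difference 3.05 (SE 0.37), edgeR, BH adjusted p = 0.00231). The death ligand TNFSF10 also had a positive difference (2.78 (SE 0.40)). CXCL5, a neutrophil-attracting chemokine, fell in MPN (log2 fold change -0.97 (SE 0.16)) and rose in healthy cells (1.16 (SE 0.20), adjusted p = 0.087 without healthy replicate 1), a difference of -2.14 (SE 0.26). The fatty acid carrier FABP4 (-3.86 (SE 0.57)) and VWA5A (-2.50 (SE 0.41)) also had negative differences.

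The test called 4 genes higher and 4 lower of 18433 (2 and 6 with library totals), 1068 at an unadjusted p under 0.05. ZNF625-ZNF20 and the pseudogenes EEF1DP3 and TEX28P2 had a group at 0 counts, and these pseudogenes, outside the rule, are named after their values were seen. EEF1DP3 with α-KG was at least 54.6-fold higher in MPN than in healthy cells and ZNF625-ZNF20 at least 34.6-fold higher, while TEX28P2 was at least 37.4-fold lower. The bound for ZNF625-ZNF20 does not cover reads assigned to ZNF625 or ZNF20 instead. EEF1DP3 overlaps FRY on the same strand, and its bound does not cover reads assigned to FRY. For TEX28P2 this bound rests on 2.5 ± 2.74 CPM (SD, n = 2) in healthy cells and was 8.41-fold without healthy replicate 1, and for EEF1DP3 it rests on 4.85 ± 3.21 CPM (SD, n = 3) in MPN cells and was 34.5-fold without MPN replicate 2. No gene passed without the replicate block, DESeq2 called 19, limma-voom 12, and 92 passed with no low-count filter. The count was 1 without healthy replicate 1, 24 without healthy replicate 2, 4 without MPN replicate 1 and 15 without MPN replicate 2. All 8 missed the threshold without healthy replicate 1, IFIT2 and CXCL5 both at an adjusted p of 0.0528, TNFSF10 at 0.138, FABP4 at 0.102, VWA5A at 0.142, EEF1DP3 at 0.134, ZNF625-ZNF20 at 0.192 and TEX28P2 at 0.476. Without MPN replicate 1, TNFSF10 and ZNF625-ZNF20 (both 0.0566), VWA5A (0.0626) and TEX28P2 (0.0781) missed it, as did TEX28P2 without MPN replicate 2 (0.174) and VWA5A without MPN replicate 3 (0.0586).

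Among lists, interferon-stimulated genes had a positive difference for 34 of 36 (median 0.94, 1 passing, 18 higher over the list alone, camera adjusted p = 3.6e-29, adjusted p = 0.343 with an estimated correlation). The mean level of the list in log2 CPM was 5.89 ± 0.38 (SD, n = 2) in healthy and 5.01 ± 1.13 (n = 3) in MPN cells in DMSO, and 3.18 ± 0.17 (n = 2) and 3.37 ± 0.49 (n = 3) with α-KG. MPN replicate 1 stood apart in DMSO, at 3.71, and without it the MPN mean was 5.66, against 5.89 in healthy cells. The median difference was 0.63 without healthy replicate 1 and 1.32 without healthy replicate 2. Macrophage maturation markers had a negative difference (median -0.90, 1 passing, 7 lower over the list alone, camera adjusted p = 5.19e-09, adjusted p = 0.244 with an estimated correlation). Of the interferon list 0 without healthy replicate 1 and 6 without healthy replicate 2 passed, and of the maturation list 3 without MPN replicate 2 and 0 without healthy replicate 1. In all 10 of 37 lists passed with camera, and none with an estimated correlation, where the smallest adjusted p was 0.244.

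Across the 18433 genes the effects of α-KG in MPN and in healthy monocytes correlated at Pearson r = 0.299 (Spearman rho = 0.384), genes not being independent replicates. Of the 1234 genes called in MPN, 1165 (94.4%) had the same sign in healthy cells. There were 246 genes higher in both, against 10.9 for independent lists, 295 lower in both, against 16.5, and 6 with opposite calls, such as CXCL5. Both sets of calls share the estimate of each gene's spread, so the numbers for independent lists are no exact reference. Among the 7303 genes with a mean log2 CPM of at least 3, r was 0.742. Leaving out healthy replicate 1 gave r = 0.153 and leaving out healthy replicate 2 gave 0.185.

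The difference between patients' and healthy monocytes in DMSO is the disease comparison. Markers of platelets and their precursor, the megakaryocyte, were higher in MPN monocyte libraries. The platelet chemokine PF4 averaged 25.3 ± 27.9 CPM (SD, n = 3) in MPN and 0.736 ± 0.963 CPM (SD, n = 2) in healthy libraries. PPBP, another platelet chemokine, averaged 191 ± 219 CPM (SD, n = 3) and 7.3 ± 5.65 CPM (SD, n = 2). Without MPN replicate 1 the MPN means were 9.58 CPM for PF4 and 66.5 CPM for PPBP. Of 18 measured platelet markers all had positive log2 differences, 14 were higher in every MPN library than in any healthy one (3 against 2 gives this by chance for 10% of genes), and 14 passed when adjusted over the list alone. The list's median was 3.41 (camera adjusted p = 1.08e-23, adjusted p = 0.544 with an estimated correlation).

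No gene of 16794 passed the threshold over all genes (edgeR, BH), with 1337 at an unadjusted p under 0.05. DESeq2 called 147, limma-voom 0, edgeR with no low-count filter 416 and with all 10 libraries 1. Without MPN replicate 1 there were 5, without MPN replicate 2 there were 2 and without healthy replicate 1 there was 1. By smallest p, the higher genes were TM4SF1 (4.93 (SE 0.79)), the incretin receptor GIPR (2.32 (SE 0.39)), the fetal globin HBG2, TREML1 of platelet granules (4.80 (SE 0.86)) and the phosphatase DUSP4 (1.93 (SE 0.37)). HBG2 had 0 counts in healthy libraries in DMSO, so it was at least 359-fold higher in MPN (25.1 ± 20.4 CPM (SD, n = 3)). Without MPN replicate 1 this bound was 239-fold. HBG2 overlaps HBE1 on the same strand, so a read can be assigned to either gene, which the bound does not cover. The lower ones were the tubulins TUBB6 (-1.94 (SE 0.29)) and TUBB4B (-1.33 (SE 0.22)), CRISPLD2 (-1.77 (SE 0.29)), MPV17L2 (-1.70 (SE 0.28)) and the decoy receptor TNFRSF10D (-1.81 (SE 0.30)), with BH adjusted p from 0.244 to 0.268 for these 10.

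Camera called 11 of 37 lists in DMSO. Higher in MPN beside the platelet list were B cell markers (median 2.69, 0.00142, and adjusted p = 0.544 with an estimated correlation), erythroid markers (2.26, 0.00667, and adjusted p = 0.544 with an estimated correlation) and T cell markers (1.13, 0.0277, and adjusted p = 0.93 with an estimated correlation). Also higher were mitochondrially encoded subunits (0.78, 2.18e-10, and adjusted p = 0.544 with an estimated correlation; 9 of 13 over the list alone) and macrophage maturation markers (0.96, 0.000275, and adjusted p = 0.544 with an estimated correlation). Lower were interferon-stimulated genes (-0.51, 2.74e-09, and adjusted p = 0.544 with an estimated correlation), heat shock genes (-0.63, 5.92e-05, and adjusted p = 0.544 with an estimated correlation) and p53 targets (-0.24, 0.00666, and adjusted p = 0.544 with an estimated correlation). Classical (-0.59, 5.69e-05, and adjusted p = 0.544 with an estimated correlation) and non-classical monocyte markers (-0.55, 0.000644, and adjusted p = 0.544 with an estimated correlation) were lower too. Over each list alone, 2 B cell, 2 erythroid and 0 T cell markers were higher, and 1 interferon-stimulated gene, 0 heat shock genes, 1 p53 target, 3 classical and 2 non-classical markers lower. Donors left out in turn moved these medians. Without MPN replicate 1 the medians of T cell markers (0.07), B cell markers (0.81) and interferon-stimulated genes (-0.16) were nearer 0, as was that of macrophage maturation markers without MPN replicate 3 (0.37). Heat shock genes had -0.38 without MPN replicate 2 and -0.30 without healthy replicate 2, p53 targets -0.13 without healthy replicate 1 and non-classical monocyte markers -0.31 without healthy replicate 2. TNF (-0.40 (SE 0.33)), IL1B (-0.36 (SE 0.70)) and CXCL8 (-0.43 (SE 0.37)) did not pass.

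**Figure D3:**
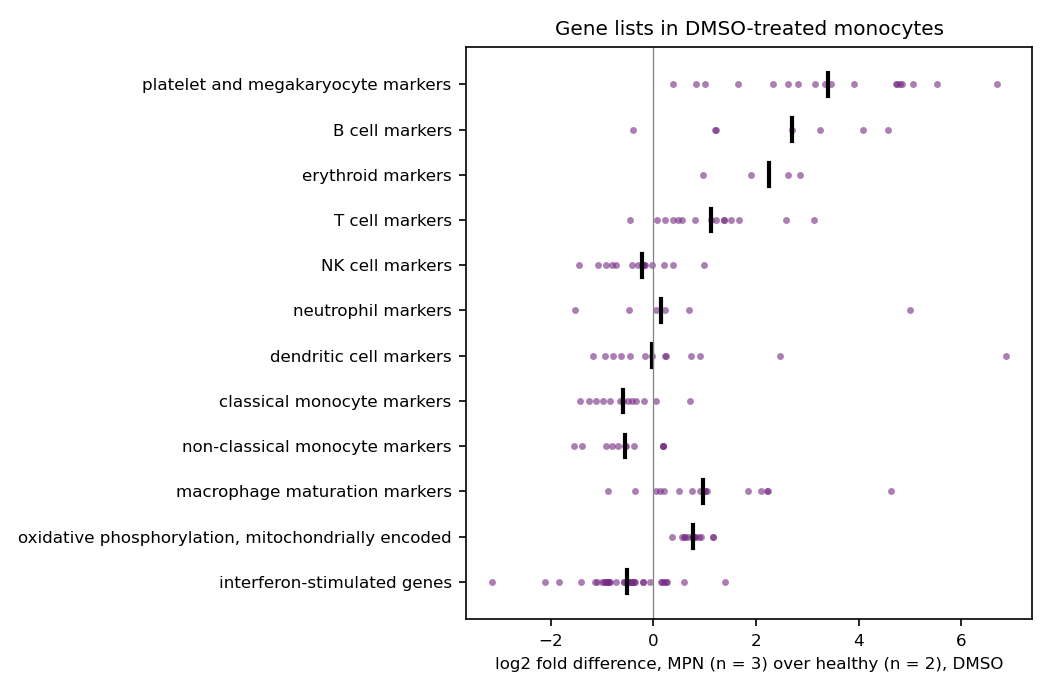
Log2 difference of MPN (3 donors) over healthy monocytes (2 donors) in DMSO for each measured member of 12 gene lists, with the median of each list as a black bar. Platelet markers lie at a median of 3.41 and all to the right of 0, whereas NK cell markers lie at a median of -0.22.

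In the α-KG libraries the same disease comparison shows which differences stood with treatment. Platelet markers were again higher in MPN, all 19 with positive log2 differences and 15 passing when adjusted over the list alone (median 3.12, camera adjusted p = 6.62e-30, adjusted p = 0.448 with an estimated correlation). PF4 differed by 4.11 (SE 0.74) and SPARC, a matrix protein stored in platelets, by 3.67 (SE 0.61), neither passing over all genes. All 13 mitochondrially encoded subunits were higher over the list alone (median 0.98, camera adjusted p = 1.32e-19, adjusted p = 0.321 with an estimated correlation), and interferon-stimulated genes had a median of 0.27 (camera adjusted p = 0.496).

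No gene of 16463 passed over all genes (edgeR, BH), with 1363 at an unadjusted p under 0.05. DESeq2 called 179, limma-voom 0 and edgeR with no low-count filter 367, and without MPN replicate 2 there was 1. By smallest p the higher genes were HBG2 (7.80 (SE 1.13)), GIPR (1.85 (SE 0.28)), SPARC, PF4 and CALD1 (6.12 (SE 1.11)). As HBG2 lay near the floor in healthy libraries (0.112 ± 0.159 CPM (SD, n = 2), 0 in healthy replicate 2), its fitted value is uncertain. The lower ones were SIGLEC12 (-5.09 (SE 0.62)), the membrane fusion protein STX1A (-2.40 (SE 0.30)), the growth factor PDGFA (-2.61 (SE 0.35)), TUBB6 (-1.84 (SE 0.26)) and BMP6 (-2.26 (SE 0.37)), with BH adjusted p from 0.094 to 0.205 for these 10. Camera called 9 lists, of which erythroid (4.56, 8.87e-05, and adjusted p = 0.448 with an estimated correlation), B cell (2.72, 0.0438, and adjusted p = 0.859 with an estimated correlation) and T cell markers (1.06, 0.0289, and adjusted p = 0.946 with an estimated correlation) were also higher. Lower were p53 targets (-0.34, 0.00275, and adjusted p = 0.448 with an estimated correlation), coagulation (-0.25, 0.0128, and adjusted p = 0.448 with an estimated correlation), heat shock (-0.27, 0.0128, and adjusted p = 0.946 with an estimated correlation) and glycolysis genes (-0.31, 0.0405, and adjusted p = 0.774 with an estimated correlation). Without MPN replicate 1 the medians were 0.26 for T cell markers, 0.74 for B cell markers and -0.17 for glycolysis genes, and without MPN replicate 2 that of heat shock genes was -0.08. Without MPN replicate 3 and healthy replicate 2, in turn, erythroid markers had 2.82 and 2.99. Without healthy replicate 1 glycolysis genes had -0.16.

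The effect of α-KG in MPN was also set against the disease difference in DMSO, which bears on whether treatment moved expression towards that of healthy cells. Across 18433 genes the correlation was r = -0.222, but the MPN libraries in DMSO enter both sides with opposite sign. In 50 simulations without any effect r ran from -0.466 to -0.431, but these drew the libraries independently, without the pairing of donors, so they are no exact reference. With the MPN donors split between the sides, r ran from -0.05 to 0.04 over 6 splits.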

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

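The test on classical monocyte markers, and the setting without rRNA-like and mitochondrial genes, were chosen after the result was seen. Interferon-stimulated genes fell with α-KG (median log2 fold change over all donors -1.95), and the effect differed between donor groups, with a median difference, MPN minus healthy, of 0.94 by camera (adjusted p = 3.6e-29, and 0.343 with an estimated correlation). Under every scaling tried and without rRNA-like and mitochondrial genes, the list's median over all donors stayed at -1.93 or below. The median of all genes lay no lower than -0.12 in these settings. This argues against a shift common to all genes as the whole explanation. Such settings move all genes nearly alike, so they test no other effect of composition. Classical monocyte markers had a median of -0.30 (SE 0.134 over 13 members), far from the fall of the interferon list. This argues against a lower share of monocytes as the whole explanation. The markers' mean log2 CPM did fall, from 7.48 to 6.92 in healthy (n = 2) and from 6.86 to 6.65 in MPN cells (n = 3). A lower share as a part of the explanation therefore stays open. The interferon list's mean log2 CPM lay further apart between the groups in DMSO, at 5.89 ± 0.38 (SD, n = 2) in healthy and 5.01 ± 1.13 (SD, n = 3) in MPN cells. With α-KG it was 3.18 and 3.37, so the difference of effects came with a difference in DMSO. Without MPN replicate 1 the MPN mean in DMSO was 5.66. What stays open, as hypotheses not tested here, is that α-KG may lower the making of interferon or the response to it in monocytes or in a rarer cell among them, and why the donor groups differed (median difference 0.63 without healthy replicate 1, 0.71 without MPN replicate 1).

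For 8 genes the effect of α-KG differed between MPN and healthy monocytes past the threshold (edgeR, BH). The log2 difference was 3.05 for IFIT2, 2.78 for TNFSF10, -2.14 for CXCL5, -3.86 for FABP4 and -2.50 for VWA5A. ZNF625-ZNF20 (8.74), EEF1DP3 (10.74) and TEX28P2 (-15.55) had a group at 0 counts, so these fitted values depend on the prior count and are no bounds. With α-KG ZNF625-ZNF20 was at least 34.6-fold and EEF1DP3 at least 54.6-fold higher in MPN than in healthy cells, and TEX28P2 at least 37.4-fold lower (8.41-fold without healthy replicate 1, and 34.5-fold for EEF1DP3 without MPN replicate 2). Reads of ZNF625-ZNF20 can also be assigned to ZNF625 or ZNF20, and those of EEF1DP3 to FRY on the same strand, which these bounds do not cover. On simulated data the test of the difference made 12 false calls among 68. Without healthy replicate 1 none of the 8 passed, with adjusted p of 0.0528 for IFIT2 and CXCL5, 0.102 for FABP4, 0.134 for EEF1DP3, 0.138 for TNFSF10, 0.142 for VWA5A, 0.192 for ZNF625-ZNF20 and 0.476 for TEX28P2. Without MPN replicate 1, TNFSF10 and ZNF625-ZNF20 (both 0.0566), VWA5A (0.0626) and TEX28P2 (0.0781) did not pass, nor TEX28P2 without MPN replicate 2 (0.174) or VWA5A without MPN replicate 3 (0.0586).

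A further 9 gene lists differed between groups by camera, none of them with an estimated correlation, and none past the threshold by fry. Median log2 differences, MPN minus healthy, were positive for NF-kB targets (0.16, adjusted p = 0.879 with an estimated correlation), cytokines and chemokines (0.70, 0.403), mitochondrially encoded subunits (0.23, 0.879), classical (0.35, 0.403) and non-classical monocyte markers (0.49, 0.343). Erythroid markers had 1.92 (0.343), and 1.93 without the member that had a group at 0 counts. LXR targets (-0.36, 0.343), lysosome and autophagy genes (-0.10, 0.343) and macrophage maturation markers (-0.90, 0.244) had negative medians. With 1 donor left out at a time, medians that came nearer 0 were 0.05 for NF-kB targets (without MPN replicate 3), 0.39 for cytokines and chemokines, 0.02 for mitochondrially encoded subunits, 0.30 for non-classical monocyte markers and 0.14 for erythroid markers (these without healthy replicate 2), with 0.43 for erythroid markers without healthy replicate 1 and 0.07 for mitochondrially encoded subunits without MPN replicate 2. Non-classical monocyte markers had 0.29 without MPN replicate 2 and cytokines and chemokines 0.41 without MPN replicate 3.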

How the results depend on the processing

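The setting without rRNA-like and mitochondrial genes, and leaving out donors from the correlation of effects, were chosen after seeing the data. Scaling by RLE or library totals, both other low-count filters, DESeq2, limma-voom and leaving out rRNA-like and mitochondrial genes gave 1181 to 1491 genes for α-KG in MPN (1234 in the main analysis), 686 to 1060 in healthy donors (809) and 1859 to 2369 over all donors (1977). With each donor group's own libraries the counts were 980 in MPN and 1384 in healthy donors. Without the replicate block they were 84 in MPN, 3 in healthy donors, 0 for the difference of effects and 318 over all donors. The difference of effects had 8 genes, 19 with DESeq2, 12 with limma-voom, 7 to 8 under the other scalings and the stricter filter, and 92 with no low-count filter. Disease in DMSO had 0 genes, but 147 with DESeq2, 416 with no low-count filter and 1 with all 10 libraries, and disease in α-KG 0, but 179 with DESeq2 and 367 with no low-count filter. Leaving out 1 donor at a time, which assumes that a lone library varies like the other groups, gave 688 to 1221 genes in MPN, 170 to 912 in healthy donors, 1 to 24 for the difference, 1272 to 1659 over all donors, 0 to 5 for disease in DMSO and 0 to 1 in α-KG. Of the lists past the threshold with camera (14 in MPN, 11 in healthy donors, 10 for the difference, 15 over all donors, 11 for disease in DMSO and 9 in α-KG), an estimated correlation left 0, 0, 0, 1, 0 and 0, while fry kept 4, 0, 0, 9, 0 and 0 of them and called 6 in MPN and 11 over all donors in all. Without the replicate block camera called 12 lists in MPN, 12 in healthy donors, 2 for the difference and 9 over all donors. The correlation of effects (r = 0.299) was 0.742 at a mean log2 CPM of at least 3 and 0.153 to 0.339 without 1 donor, and the correlation of α-KG with disease (-0.222) averaged -0.0150 with the MPN donors split. For these counts and correlations the cause was not tested, except that the split removes the shared libraries and leaving out a donor leaves fewer samples. Single named genes past the threshold kept their direction and call in 3611 gene and setting pairs and lost the call in 622, with 0 reversed. Of the lost calls 1, HBB in healthy monocytes, had a fitted change of 0 without healthy replicate 1. There the healthy donor left had 0 counts of it. For the other lost calls the cause was not tested. Named genes not past the threshold stayed so in 8822 pairs, passed in 348 and moved by more than their SE to the other sign in 51. Smaller changes were mostly out of reach with these libraries, whether for depth or for the spread between donors was not tested, since simulated 1.5-fold changes were recovered at 29.9% over all donors, 19.4% in MPN, 5.97% in healthy donors, 1.49% for the difference and for disease in DMSO, and 0% for disease in α-KG.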

Other observations

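The tests on RNAs without a poly(A) tail, on proliferation genes and on NK cell markers were chosen after the result was seen. Over all donors, the genes that passed with α-KG leaned upward among non-coding kinds and downward among protein-coding genes (edgeR, BH). Of 1063 lincRNA genes 88 were higher and 14 lower, of 1249 antisense genes 88 and 19, and of 13207 protein-coding genes 530 and 1030. Named after their values were seen, the signal recognition particle RNA RN7SL1 rose by 1.06 on the log2 scale (SE 0.11), the RNase MRP RNA RMRP by 1.12 (SE 0.15) and the inhibitor of transcription elongation HEXIM1 by 1.64 (SE 0.12), while RPPH1 (-2.49, SE 2.23) and MALAT1 (0.26, SE 0.10) did not pass.

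Of the 10 ways to part the 6 MPN libraries into 3 and 3, 1 gave as many genes as the real split (1234), the real one itself, and the highest other gave 0, but 10 splits are too few for a share under 0.05. Of 100 splits of all 10 libraries into 5 and 5, 1 gave as many as the real one (1977), the real one itself, and the highest other gave 29. Among the 15 of these that part every pair, as the real one does, the highest other gave 0, but 15 are too few for a share under 0.05. The others put both libraries of some donors on the same side, so they are no like-for-like comparison.

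Replication-dependent histone genes, a set put together after its values were seen, had 41 of 61 higher and 0 lower over all donors (median 1.14, SE 0.139 over members), with 41 higher in MPN (median 1.41) and 20 in healthy donors (median 0.86). Proliferation genes had a median of 0.12 (SE 0.17 over members), which argues against a rise of the list as a whole. It argues only weakly against entry into S phase, since the list also holds genes of mitosis. Its level was low too, at a mean log2 CPM of 1.44 in both donor groups in DMSO. Other RNAs without a poly(A) tail (94 snRNA, snoRNA, scaRNA and misc_RNA genes) had a median of 0.74 (SE 0.103), as an increase in the reading of RNA without such a tail would give. The rise was uneven, as the 52 misc_RNA genes among them had a median of only 0.35 (5 higher, 0 lower). Of 8 blood markers of a response to perturbed P-TEFb or BET proteins 7 had the predicted sign and 2 of them passed, CCR1 (-0.86) and CD180 (-1.03, but adjusted p = 0.0563, 0.0788 and 0.0901 without MPN replicate 1, 2 and 3), while DCXR passed the other way (0.73, but 0.17 without healthy replicate 1 and 0.148 and 0.0765 without MPN replicate 1 and 2). Fewer than 3 passing had been set beforehand to count against that response, but a missed threshold excludes no change (SERPINI1 1.08, SE 0.66; PDCD1LG2 -1.55, SE 1.01), and HEXIM1, whose rise was seen before, does not count for it, so it stays open, as do the reading of more RNA without a poly(A) tail, the selection of RNA being unstated, and another change by α-KG in how histone RNA is made or kept.

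Platelet markers were higher in MPN than in healthy monocytes in DMSO, with a median of 3.41 (SE 0.521 over 18 members), and the most abundant, PPBP, averaged 191 ± 219 CPM (SD, n = 3) against 7.3 ± 5.65 CPM (SD, n = 2), the MPN mean being 66.5 CPM without MPN replicate 1. In this comparison 0 of 16794 genes passed over all genes (edgeR, BH). The list did not pass by camera with an estimated correlation (adjusted p = 0.544). Without 1 MPN donor at a time the lowest median was 2.41, which argues against a single donor as the whole of the list's difference. NK cell markers had a median of -0.22 (SE 0.198 over 15 members), against 1.13 for T cell (15 members), 2.26 for erythroid (4) and 2.69 for B cell markers (7). Without MPN replicate 1 the T cell, erythroid and B cell medians were 0.07, 1.76 and 0.81. The gap between NK cell and platelet markers argues against a lower share of monocytes that raises every other cell type alike. These SEs over members do not measure the spread between donors. Classical monocyte markers averaged a log2 CPM of 6.86 ± 0.33 (SD, n = 3) in MPN against 7.48 ± 0.02 (SD, n = 2). Non-classical markers averaged 3.695 ± 0.28 (SD, n = 3) against 4.275 ± 0.24 (SD, n = 2). A lower share of monocytes that raises other cell types unevenly therefore stays open. Of the 18 members 9 reached 1 CPM in healthy DMSO libraries too, and 0 belonged to another list. What stays open, as hypotheses, is that platelets may have been bound to or isolated with the monocytes, CD14+ being the only selection named, and that monocytes themselves may differ in MPN, which was not tested.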
